A study of Mus musculus with 6 samples.

How the data were processed

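Total RNA from sorted HB9::GFP motor neurons was labelled with biotin by a whole-transcript kit and hybridised to arrays, per the labels' protocols, with 1 array for each of 3 medial and 3 lateral samples of lumbar cord from embryonic day 12. The authors deposited one table of processed values per transcript-level row and array, and its unit was taken to be log2 from the range of the values, 2.49 to 14.1. The method of summarization, background correction and normalization was not given in the sources used here, and any centring between arrays therefore stays unknown. The medians of the deposited log2 values were 6.82, 6.73 and 6.78 for medial replicates 1, 2 and 3 and 6.84, 6.77 and 6.76 for lateral replicates 1, 2 and 3. The genome build was mm9, per the submitters' processing notes. The series design names a comparison of medial with lateral motor neurons by the program PowerExpress, with a fold change of at least 1.5 and a false discovery rate whose value it leaves open. That program was not run here.

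Groups and replicate numbers were taken from the sample titles. The table gives no detection calls, so no row was left out in the main test, and a level near those of genes of other tissues can be background. Each array's value table is one measurement per transcript, and the number of arrays limits the precision. Pairs of samples shared at most 7 identical values of 23332, so no array was treated as a copy of another. The p-values measure the spread between these samples, and the labels do not say whether replicates came from separate litters.

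The deposited values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, medial minus lateral, without a block), with Benjamini-Hochberg adjustment over all 23332 rows and a threshold of 0.05. A second count asked for a fold of at least 1.5 as well. Errors given with log2 differences are standard errors from this fit, and those given with group means are SDs over 3 samples. Genes were named through the platform's probe table. Of the 23332 rows, 14996 had 1 gene symbol, 1019 had several and 7317 were not listed there. The unlisted rows include 6577 with identifiers below those of the listed rows and a median level of 5.62, against 7.35 for listed rows. They could not be told to be controls and were kept. Of the rows with 1 symbol, 14941 had an Entrez identifier found in the RefSeq gene table of assembly GRCm38.p6, which supplied current symbols, and 55 kept the symbol of the probe table. That table served only for names and for which genes neighbour each other. Rows with several symbols were not named. Where a gene had more than 1 row, the row with the highest mean over the 6 samples stood for it, which gave 14860 genes, 135 of them with more than 1 row. In 5 of these the rows differed in their call, and in 0 they were called in opposite directions.

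Before the data were examined, 31 gene lists were fixed, which covered motor column identity, Hox genes, axon guidance and adhesion, growth factor receptors, signalling pathways, neuronal maturation, other cell types and the state of RNA and cells. They held 627 different genes, of which 517 had a row with a single symbol. Each list was tested with limma's camera at its preset correlation of 0.01 on 1 row per gene, adjusted over the 31 lists, which gave 5 lists past the threshold. With a correlation estimated from the data 0 of the 31 passed in camera, where 3 of them, the medial column, lateral column and floor plate lists, had an unadjusted p under 0.05, and with fry 6 passed. Fry asks whether the genes of a list move on balance in one direction, and does not compare the list with other genes. The median, the mean and the test differed in sign for the lists of general motor neuron genes, of semaphorins, plexins and neuropilins, of netrin, Slit and Robo genes, of the retinoic acid pathway, and of progenitor, mesenchyme and cartilage, and myeloid genes, which did not pass. Members past the threshold were counted over all rows and adjusted over the list alone.

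The rule for the genes named in the text was also fixed before the data were examined. It took, first, the 15 largest rises and 15 largest falls among rows with a single symbol that was not a predicted, clone or olfactory or vomeronasal receptor name, that passed the threshold and whose groups did not overlap, to be filled to 10 by the smallest p where fewer passed. It also took every measured member of the medial and lateral column lists, and last, up to 6 members with the smallest p of every other list. Of the last kind, the text names the members that passed and some that did not, and it says where a gene outside the rule was chosen after its values were seen.

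Before use, the test was tested on simulated data with the means of the real rows and their variances as moderated by limma. Errors were drawn from a normal distribution, independently between rows and samples. Real rows can depart from this, so the shares recovered need not hold for them. For the comparison of medial with lateral samples over 23332 rows, it recovered 34.3% of 67 rows changed 1.5-fold, 86.6% of 67 rows changed 2-fold and 95.5% of 66 rows changed 4-fold, with 11 calls among unchanged rows.

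The alternatives chosen before the data were examined were the replicate number as an additive or a random block, quantile normalization and median centring on top of the deposited values, the removal of rows whose mean lay below the 25th percentile or the median (50th percentile), an intensity trend with robust variance, array weights, each sample left out in turn, both samples of a number left out with the block, an adjusted p of 0.10, 1 row per gene, other gene set tests and the row with the largest variance for a gene. For the random block and the robust fit, camera was run on the moderated statistics of the fit. A count over only the rows with a gene name was added after the data were seen.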

Results

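Gene expression was measured in motor neurons of the lumbar spinal cord of mouse embryos on embryonic day 12. The embryos carried HB9::GFP, a transgene that labels motor neurons with green fluorescent protein, and the neurons were obtained by dissecting the cord into columns and sorting fluorescent cells. The 6 arrays comprised 3 samples of medial and 3 samples of lateral motor neurons, which the labels call biological replicates. Motor neurons of the medial column innervate the muscles along the spine, and those of the lateral column innervate the limb. The table held 23332 transcript-level values per array on a log2 scale, from 2.49 to 14.1. The median of the 6 arrays lay between 6.73 and 6.84. Within a group, 2 samples correlated over all values with r between 0.987 and 0.993. A medial and a lateral sample correlated with r between 0.980 and 0.988, so the ranges overlapped. The first principal component, with 42.5% of the variance, separated the medial from the lateral samples. The number of arrays limits the precision of each difference.

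The comparison asked which transcripts differ between medial and lateral motor neurons at this stage. Sema3d, which encodes a secreted guidance semaphorin, was 13.7-fold higher in the medial samples (log2 difference 3.77 ± 0.10, SE, 3 samples per group, adjusted p = 5.89e-05). Uts2, which encodes the peptide urotensin 2, was 11.98-fold higher, and the transcription factor genes Mecom and Lhx3 were 9.71-fold and 9.41-fold higher. In the opposite direction, Aldh1a2, whose enzyme makes retinoic acid, was 29.3-fold higher in the lateral samples (log2 difference −4.87 ± 0.32, SE, adjusted p = 0.00112). Brinp3 was 28.0-fold, the muscarinic receptor gene Chrm3 10.7-fold and the copine gene Cpne4 10.2-fold higher in the lateral samples. In 22 of the 30 genes with the largest measured differences, those just named except Aldh1a2 among them, the mean of the dimmer group was no higher than the highest mean of a skeletal muscle gene (7.44 on the log2 scale), a level that cannot be separated from background here. Their folds can therefore understate the difference, and the order of the genes by fold is not settled. The bound of 7.44 is high, since the median level was 5.74 for the skeletal muscle genes and 7.35 for all listed rows. A dimmer group below it need not be at background. In all, 717 rows passed an adjusted p of 0.05 in limma, 264 higher and 453 lower in the medial samples. Of these, 628 also differed by at least 1.5-fold, 241 upward and 387 downward. The 717 rows include 117 that were not listed in the probe table. Of those, 101 had the low identifiers described above, so it is not known whether they are controls, and 82 of the 101 were lower. Among genes with a single symbol, 228 were higher and 336 lower in the medial samples. The values of the medial and lateral samples did not overlap in 19.3% of all rows, where chance gives 10%. The count of 717 fell to 361, 377 and 326 without medial replicate 1, 2 or 3. It fell to 484, 407 and 538 without lateral replicate 1, 2 or 3.

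The other genes with the largest measured differences in favour of medial neurons came from several functional classes. Klhl1, a kelch-like gene, was 6.64-fold higher, and the zinc finger gene Sp8 was 6.43-fold higher. Nxph4, which encodes a neurexophilin, a ligand of neurexins, was 6.41-fold higher, and Hoxc13 was 6.33-fold higher. A separate row with the older symbol Mds1, a name for part of the Mecom locus, was 6.28-fold higher. Lhx4, Fam163a and the growth factor gene Fgf9 were 5.84-fold, 5.74-fold and 5.64-fold higher. Fstl4, Prss35 and the basic helix-loop-helix gene Neurod1 differed by 4.65-fold, 4.39-fold and 4.25-fold.

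Among those in favour of lateral neurons, Lgi1, which encodes a secreted synaptic protein, was 9.86-fold higher, and Kitl, which encodes the ligand of the receptor Kit, was 9.31-fold higher. The transcription factor gene Foxp1 was 8.01-fold higher. Sst, which encodes the peptide somatostatin, was 7.67-fold higher, and reached a mean of 12.2 ± 0.26 (log2, SD, n = 3) in the lateral samples against 9.27 ± 0.30 in the medial samples. Rgs4, a regulator of G protein signalling, was 7.65-fold higher, followed by Ppp1r1c at 7.64-fold, the carbonic anhydrase-related gene Car10 at 7.63-fold and the homeobox gene Irx6 at 7.54-fold. Bnc2, the neurokinin receptor gene Tacr3 and Mgat4c differed by 7.18-fold, 7.10-fold and 6.53-fold. For these genes with the largest differences, in both directions, the naming rule itself required that the 3 medial and 3 lateral values did not overlap. Their calls held whichever single sample was left out.

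**Figure D1:**
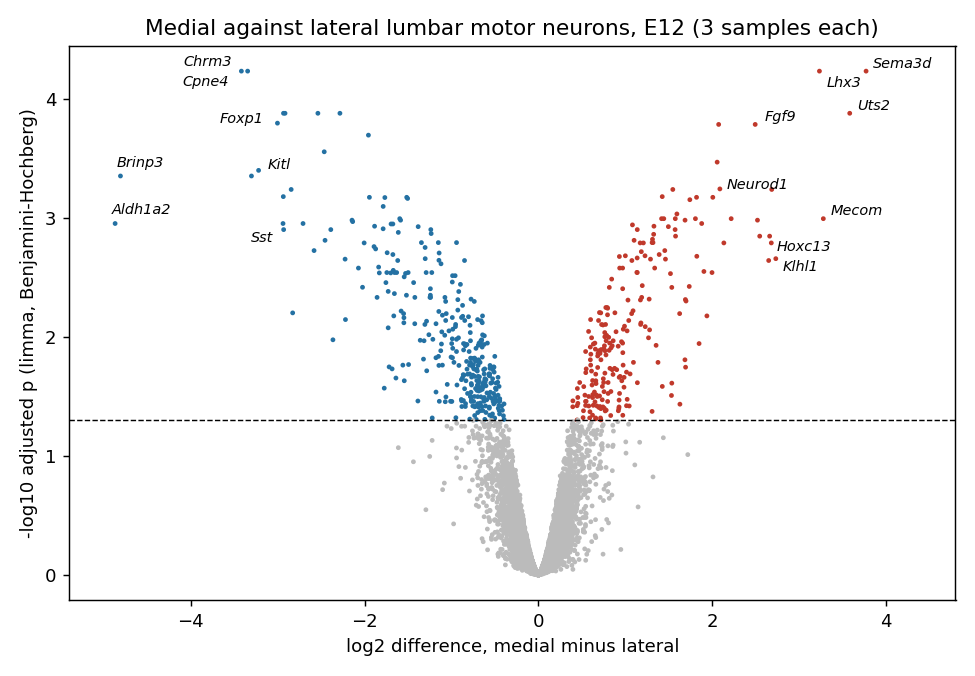
Each point is a gene with a single symbol. The horizontal axis gives the log2 difference, medial minus lateral, and the vertical axis −log10 of the adjusted p from limma. The dashed line marks an adjusted p of 0.05, red points are higher and blue points lower in the medial samples, and grey points did not pass. Of 14860 genes, 228 were higher and 336 lower, with Sema3d at 3.77 and Aldh1a2 at −4.87 at the ends.

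Of the 8 genes on the medial column list, 5 passed as higher in the medial samples and 1 as lower, 2 did not pass, and adjusted over the list alone 6 were higher and 1 lower. The gene set test camera gave the list an adjusted p of 1.38e-05 with its preset correlation and an adjusted p of 0.293 with an estimated correlation. Lhx3 and Lhx4, the LIM homeodomain genes that specify the medial column, stood at 10.4 ± 0.09 and 10.9 ± 0.06 (log2, SD, n = 3) in the medial samples and at 7.19 ± 0.10 and 8.40 ± 0.37 in the lateral samples. Mecom differed by 3.28 on the log2 scale. Epha3, an Eph receptor of medial column axons, was 2.72-fold higher, and the growth factor receptor gene Fgfr1 was 1.57-fold higher (adjusted p = 0.0352). The call of Fgfr1 ended when any one of the 6 samples was left out, with an adjusted p of up to 0.139. Tshz1 went against the list and was 3.19-fold higher in the lateral samples (log2 difference −1.67 ± 0.11, SE, adjusted p = 0.00113). Prdm16 and Sall3 did not pass, with log2 differences of 0.33 ± 0.11 and −0.04 ± 0.08. The median of the list was 1.05 on the log2 scale.

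Of 14 measured lateral column genes, 6 passed as lower in the medial samples and 1 as higher, 7 did not pass, and adjusted over the list alone 9 were lower and 1 higher. Camera gave an adjusted p of 3.15e-09 with the preset correlation and an adjusted p of 0.293 with an estimated correlation. Foxp1, which defines the lateral column, stood at 12.2 ± 0.02 in the lateral samples and 9.18 ± 0.20 in the medial samples (log2, SD, n = 3). Aldh1a2 stood at 12.4 ± 0.23 and 7.52 ± 0.65. Lhx1, a marker of the lateral division of this column, was 5.98-fold higher in the lateral samples. The motor pool genes Etv4, Cdh20 and Sema3e were 5.80-fold, 5.52-fold and 3.001-fold higher there. Pou3f1 went the other way and was 2.20-fold higher in the medial samples (log2 difference 1.14 ± 0.08, SE, adjusted p = 0.00126). Hoxd10, at −0.55 ± 0.11 with an adjusted p of 0.0553, Nkx6-2 at −0.52 ± 0.13, Crabp1 at −0.40 ± 0.14 and Hoxc10 at −0.34 ± 0.13 did not pass, nor did Epha4 at 0.15 ± 0.09, Cdh8 at 0.06 ± 0.14 and Met at 0.02 ± 0.12. Hoxd10 passed in 8 of the 10 alternatives that kept all samples and the threshold (adjusted p from 0.0141 to 0.0855) and in 0 of the 6 fits with a sample left out (0.0678 to 0.204). Nkx6-2 passed in 1 of those 10, with 1 row per gene (0.0475, range up to 0.217), and without lateral replicate 2 (0.0386, range up to 0.372). The median of the list was −0.53 on the log2 scale.

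**Figure D2:**
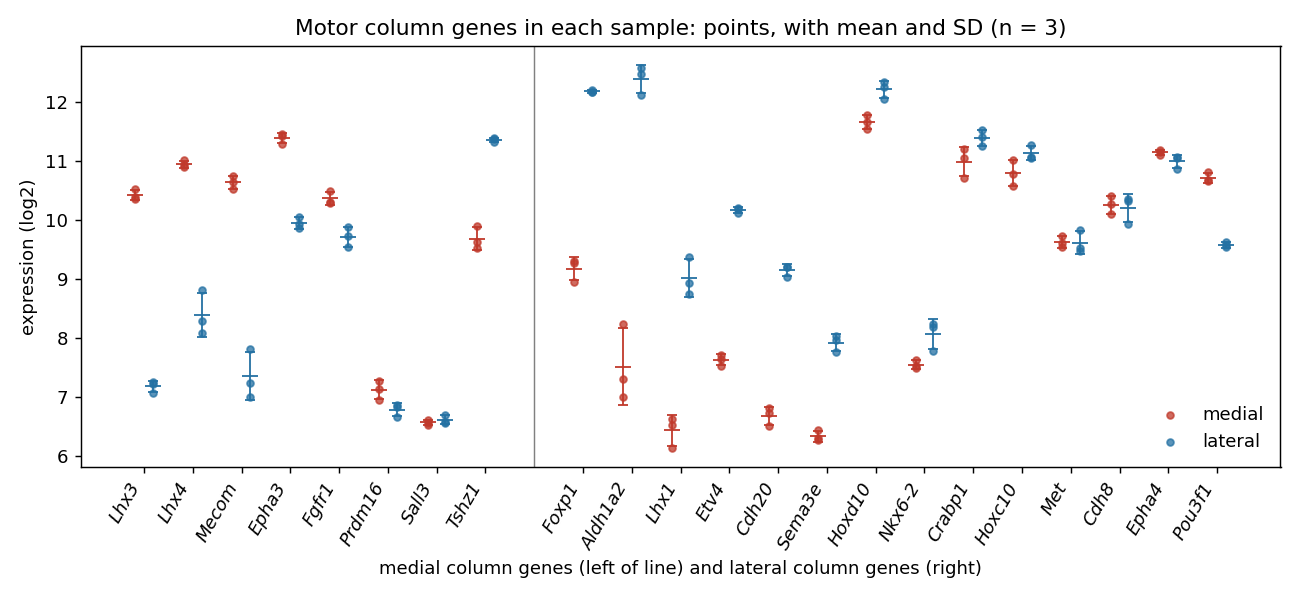
Log2 expression of the 8 medial column genes and the 14 lateral column genes in each of the 6 samples. Points are samples, horizontal marks the group means and bars the SD (n = 3), with medial samples in red and lateral samples in blue. Lhx3, Lhx4 and Mecom lie apart in the medial direction, Foxp1, Aldh1a2, Lhx1 and Etv4 in the lateral direction, and Tshz1 and Pou3f1 run against their lists.

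Genes used by motor neurons in general differed in both directions. Of 15 measured genes, 3 were higher and 4 lower in the medial samples, and adjusted over the list alone 4 and 5. The homeobox genes Isl2 and Mnx1, the latter the gene of the HB9 protein, were 2.98-fold and 2.67-fold higher in the medial samples, and Lmo4 was 2.50-fold higher. Prph, which encodes peripherin, and Ret, the receptor subunit for glial cell line-derived neurotrophic factor, were 3.15-fold and 2.36-fold higher in the lateral samples. Isl1 and Nrp1 were 1.56-fold and 1.50-fold higher there. The call of Nrp1 ended without medial replicate 1, medial replicate 3 or lateral replicate 2, with an adjusted p of up to 0.0658. The cholinergic genes Chat and Slc18a3, named after their values were seen, differed by 0.29 ± 0.07 and 0.14 ± 0.08 on the log2 scale and did not pass (adjusted p = 0.128 and 0.563). The list as a whole did not pass (camera adjusted p = 0.864).

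Of 18 measured ETS and LIM transcription factors and their cofactors, 5 were higher and 5 lower, and adjusted over the list alone 5 and 6. Besides Lhx3, Lhx4, Isl2 and Lmo4, the LIM cofactor gene Ldb2 was 2.92-fold higher in the medial samples. The LIM-only gene Lmo1 was 5.24-fold higher in the lateral samples, which also had more Etv4, Lhx1 and Isl1. Lmo3, named here after its value was seen because it completes this count, had a log2 difference of −1.83 ± 0.16. With members in both directions the list had a camera adjusted p of 0.965. In fry, which does not compare the list with other genes, its adjusted p was 0.00263. The mean and median log2 differences of the list were 0.0094 and 0.015, so the fry result is not read as a shift of the list.

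Among the Hox genes, which set position along the body axis, Hoxc13 was 6.33-fold higher in the medial samples, and its call held whichever single sample was left out. Of 13 measured genes of paralog groups 9 to 13, 2 were higher and 1 lower in the medial samples, and adjusted over the list alone 4 and 2. Hoxc13 had a log2 difference of 2.66 ± 0.19 (SE, adjusted p = 0.00143), and its mean was 9.95 ± 0.21 (SD, n = 3) in the medial samples and 7.29 ± 0.34 in the lateral samples. Hoxb13 was 1.66-fold higher in the medial samples, and Hoxa11 was 1.38-fold higher in the lateral samples. The call of Hoxb13 ended without any one of the samples other than lateral replicate 3, and that of Hoxa11 without any one of the 6, with adjusted p-values of up to 0.12 and 0.111. Hoxc12, with a mean of 12.4 in the medial samples, differed by 1.04 ± 0.20 and did not pass (adjusted p = 0.0542). It passed in 6 of the 10 alternatives that kept all samples and the threshold (adjusted p from 0.0111 to 0.083), and of the fits with a sample left out in the 1 without lateral replicate 2 (0.02, range up to 0.197). Of 13 measured genes of groups 4 to 8, 0 passed over all rows in limma and 0 when adjusted over the list alone, and their median log2 difference was 0.10. The smallest unadjusted p in that list was 0.00518, for Hoxb5, which passed in 3 of the 10 alternatives (adjusted p from 0.0358 to 0.128). Camera gave adjusted p-values of 0.472 for the posterior list and 0.843 for the anterior list.

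**Figure D3:**
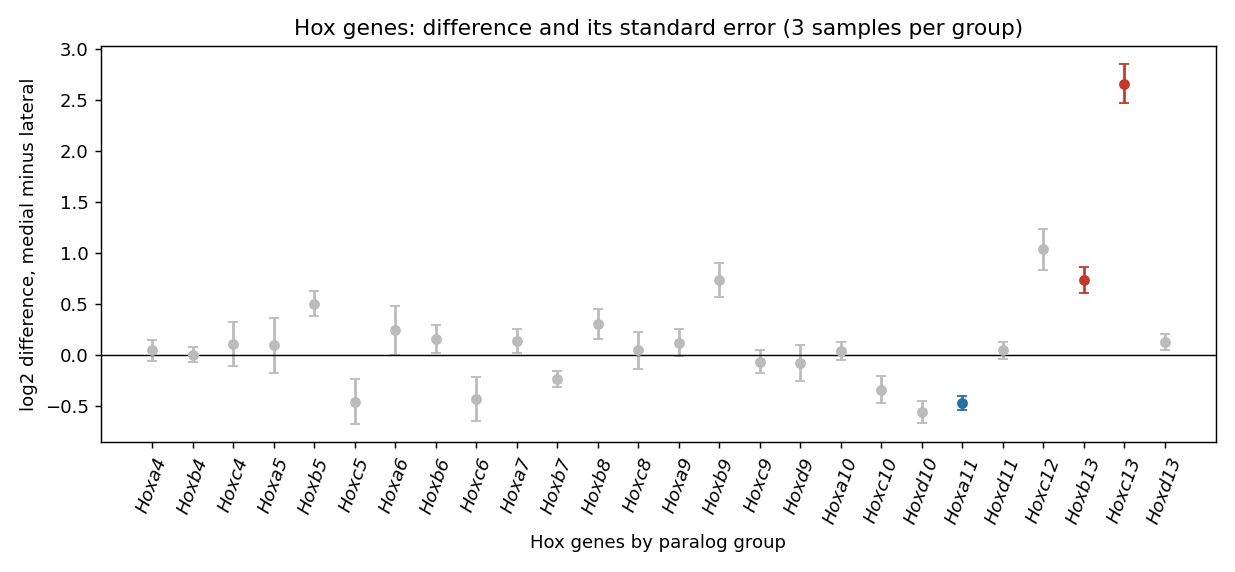
Log2 difference, medial minus lateral, of the 13 measured Hox genes of groups 4 to 8 and the 13 of groups 9 to 13, ordered along the horizontal axis by paralog group, with bars for the standard error from limma (3 samples per group). Red and blue points passed as higher and lower in the medial samples, and grey points did not pass. Hoxc13 stands at 2.66, far above the other Hox genes.

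Axon guidance genes differed in both directions within each family. Among 27 semaphorins, plexins and neuropilins, 3 were higher and 3 lower in the medial samples, and adjusted over the list alone 4 and 7. Sema3d and Sema3e differed in opposite directions, by 3.77 and −1.59 on the log2 scale, and Sema5a was 2.92-fold higher in the lateral samples. Sema6a and Sema3a were 1.58-fold and 1.56-fold higher in the medial samples. Among 19 Eph receptors and ephrins, 2 were higher and 2 lower, and adjusted over the list alone 4 and 4. Epha3 and Epha5 were 2.72-fold and 2.11-fold higher in the medial samples, and the ligand gene Efna5 and the receptor gene Epha8 were 1.99-fold and 1.58-fold higher in the lateral samples. Among 19 genes of the netrin, Slit and Robo families and their partners, 3 were higher and 5 lower, and adjusted over the list alone the counts were again 3 and 5. The netrin receptor genes Unc5c and Unc5a were 3.02-fold and 2.10-fold higher in the lateral samples, with Dscam at 1.997-fold and Robo2 at 1.94-fold, whereas the netrin receptor gene Dcc was 1.89-fold and Flrt2 2.82-fold higher in the medial samples. Neo1 at −0.49 and Flrt1 at 0.97 complete these counts and were named after their values were seen. The camera adjusted p-values of the 3 lists were 0.497, 0.383 and 0.916, and fry gave 0.0422 for the Eph receptors and ephrins. The calls of Sema3a, Sema6a, Epha8, Dcc, Neo1 and Flrt1 ended in at least one of the fits with a sample left out, with largest adjusted p-values of 0.128, 0.0713, 0.0589, 0.0623, 0.0992 and 0.168. Medial replicate 1 and medial replicate 3 ended each of them.

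Of 19 measured cadherins, the adhesion molecules that differ between motor pools, 6 passed as lower in the medial samples and 1 as higher, 12 did not pass, and adjusted over the list alone 9 were lower and 3 higher. The median log2 difference of the list was −0.14, and the camera adjusted p was 3.72e-04 with the preset correlation, a call that was lost with an adjusted p of 0.715 with an estimated correlation. Cdh20 and the protocadherin gene Pcdh17 were 5.52-fold and 5.48-fold higher in the lateral samples, and Cdh7, Cdh22 and Cdh10 were 3.19-fold, 2.21-fold and 1.72-fold higher there. Cdh4, named because it completes the count, had a log2 difference of −0.72. Cdh13 was 2.20-fold higher in the medial samples. The call of Cdh22 ended without medial replicate 3, lateral replicate 1 or lateral replicate 2 (adjusted p up to 0.0645), and that of Cdh4 without any one sample other than lateral replicate 3 (up to 0.0817).

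Among 39 receptors for neurotrophic and growth factors, 3 were higher and 3 lower in the medial samples, and adjusted over the list alone 8 and 5. Fgfr2 and the cytokine receptor subunit gene Il6st were 2.45-fold and 2.27-fold higher in the medial samples. Gfra3 and Gfra1, coreceptors for the ligands of Ret, were 4.01-fold and 1.65-fold higher in the lateral samples, as was Ret. The camera adjusted p was 0.472, and the call of Gfra1 ended without any one sample other than medial replicate 1 (adjusted p up to 0.119). Among 15 measured genes of the retinoic acid pathway, 2 were higher and 2 lower, and adjusted over the list alone 3 and 3. The enzymes Aldh1a2 and Aldh1a3 both make retinoic acid and differed in opposite directions, since Aldh1a3 was 2.53-fold higher in the medial samples and Aldh1a2 was 29.3-fold higher in the lateral samples. The receptor gene Rxrg was 2.90-fold higher in the medial samples, and Rdh10, whose enzyme makes retinaldehyde, was 2.32-fold higher in the lateral samples. The call of Rxrg ended without any one of the medial samples or lateral replicate 1 (adjusted p up to 0.0949), and the camera adjusted p of the list was 0.497.

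Among 30 Wnt ligands, Frizzled receptors and related receptors, 2 were higher and 1 lower, also when adjusted over the list alone. The receptor gene Ror1 was 2.74-fold and the ligand gene Wnt7b 1.51-fold higher in the medial samples, and Wnt3 was 2.17-fold higher in the lateral samples. The call of Wnt7b ended without medial replicate 1 or 2 or lateral replicate 1 or 2 (adjusted p up to 0.0758). Among 17 Notch pathway genes, 2 were higher and 0 lower in limma, and adjusted over the list alone 4 and 0. Jag1 and Mfng, a ligand and a modifier of the receptor, were 1.58-fold and 1.65-fold higher in the medial samples, with adjusted p-values of 0.0488 and 0.0499 that rose to 0.132 and 0.182 when single samples were left out and that passed in 0 of those 6 fits. The call of Mfng also ended after quantile normalization (0.083) and after centring of each array (0.0669). Camera gave adjusted p-values of 0.855 and 0.145 for the Wnt and Notch lists, and 0.0444 for the latter without lateral replicate 2.

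Among 25 neuronal maturation genes, 1 was higher and 4 lower in the medial samples, and adjusted over the list alone 1 and 5. Syt4, a synaptotagmin of secretory vesicles, was 3.71-fold higher in the lateral samples, with Syn2 at 1.76-fold, the heavy neurofilament gene Nefh at 1.72-fold and Snhg11 at 1.38-fold. Rbfox3, which encodes the neuronal antigen NeuN, was 1.43-fold higher in the medial samples. The camera adjusted p was 0.145, and the list passed after quantile normalization (0.05 as rounded) and without lateral replicate 3 (0.0261), where the alternatives that kept camera's preset correlation reached 0.376. Apart from that of Syt4, these calls ended in at least 4 of the 6 fits with a sample left out, medial replicate 1 and 2 among them, with adjusted p-values of up to 0.0878 for Syn2, 0.0949 for Nefh, 0.172 for Snhg11 and 0.177 for Rbfox3.

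Some markers of other cells that the dissection could carry along were called, where 564 of all 14860 genes with a single symbol were called. Lateral replicate 3 had the highest median, taken over genes as deviations from each gene's mean, in 9 of the 11 lists of other cell types, with 0.219 for interneuron, 0.184 for skeletal muscle, 0.177 for neural crest and Schwann cell, 0.173 for mesenchyme, 0.13 for sensory ganglion and 0.112 for endothelial genes. The exceptions were floor plate and progenitor genes. Over all rows below the median level, this deviation was 0.03 in that sample and between −0.022 and −0.0019 in the others. Among 20 progenitor genes, 1 was higher and 2 lower in the medial samples, also when adjusted over the list alone. Id4 and Nkx6-1 were 1.99-fold and 1.69-fold higher in the lateral samples, and Sox2 was 1.55-fold higher in the medial samples. Among 26 spinal interneuron genes, 1 was higher and 0 lower, also when adjusted over the list alone. It was Slc17a6, the gene of a vesicular glutamate transporter, at 2.03-fold. Among 13 sensory ganglion genes, 1, Neurod1, was higher and 0 lower, also when adjusted over the list alone. Its mean was 11.1 ± 0.05 in the medial samples and 9.03 ± 0.17 in the lateral samples (log2, SD, n = 3). The camera adjusted p-values of these 3 lists were 0.855, 0.25 and 0.472. Without lateral replicate 1 the interneuron list passed as lower (adjusted p = 0.0011), and without lateral replicate 3 the sensory list passed as higher (0.0236). The call of Slc17a6 ended without medial replicate 3 (adjusted p = 0.0516), that of Nkx6-1 without any one sample other than lateral replicate 3 (up to 0.0897) and that of Sox2 without any one of the 6 (up to 0.113).

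Of 9 measured floor plate genes, 3 passed as lower in the medial samples, 0 as higher and 6 did not pass, also when adjusted over the list alone. The median log2 difference of the list was −0.16, and the camera adjusted p was 4.26e-04 with the preset correlation, a call that was lost with an adjusted p of 0.293 with an estimated correlation. Spon1, Fbn2 and Shh, the gene of the signalling protein sonic hedgehog, were 2.47-fold, 2.11-fold and 2.04-fold higher in the lateral samples. Of 13 neural crest and Schwann cell genes, 2 were lower and 0 higher, also when adjusted over the list alone. They were Gfra3, the Ret coreceptor gene named above, and Postn at 1.56-fold, with means of 4.38 and 5.03 within the range of the skeletal muscle genes, whose call ended without medial replicate 1 or 3 (adjusted p up to 0.0532). The camera adjusted p of this list was 0.0168, and it was lost with an adjusted p of 0.715 with an estimated correlation. It was also lost in fry (adjusted p = 0.0649), after quantile normalization (adjusted p = 0.0586), with dim rows left out (0.102 and 0.057), without medial replicate 1 (0.0801) and without lateral replicate 3 (0.11).

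Among 20 endothelial genes, 1 was higher and 0 lower, also when adjusted over the list alone, and it was Cldn5 at 1.36-fold. Among 11 pericyte and smooth muscle genes, 0 were higher and 1 lower, and adjusted over the list alone 1 and 1. Rgs5, a paralog and genomic neighbour of Rgs4, was 3.40-fold higher in the lateral samples. Among 27 mesenchyme and cartilage genes, 1 was higher and 1 lower, also when adjusted over the list alone, with Dcn 2.48-fold higher in the medial samples and Meox2 1.47-fold higher in the lateral samples. The calls of Cldn5, Dcn and Meox2 ended when any one of the 6 samples was left out, with adjusted p-values of up to 0.124, 0.144 and 0.0878. Of 16 skeletal muscle, 11 erythroid, 15 myeloid and 25 cell cycle genes, 0 passed in limma over all rows or when adjusted over the list alone, and the smallest unadjusted p-values were 0.141 for Tnnc1, 0.117 for Tfrc, 0.149 for Cd68 and 0.00518 for Mcm2. Mcm2 passed in 4 of the 10 alternatives that kept all samples (adjusted p from 0.0417 to 0.118). The camera adjusted p-values were 0.648 for endothelial, 0.383 for pericyte, 0.654 for mesenchyme, 0.472 for skeletal muscle, 0.472 for erythroid, 0.864 for myeloid and 0.472 for cell cycle genes. Without lateral replicate 1 the skeletal muscle list passed as lower (adjusted p = 0.0433). The mean levels of the skeletal muscle genes ran from 3.71 to 7.44 on the log2 scale. Those of the endothelial genes, Cldn5 among them, reached at most 7.19, within that range. Those of the mesenchyme and cartilage genes, Dcn and Meox2 among them, reached at most 7.49.

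Genes that report on the state of the cells and RNA showed 0 calls in limma over all rows and when adjusted over the list alone. This held for 22 dissociation and stress genes, 12 ribosomal protein genes, 28 oxidative phosphorylation genes and 2 measured sex chromosome dosage genes, with median log2 differences of 0.08, 0.03, 0.02 and 0.17. The smallest unadjusted p in these lists was 0.00524, for the stress list gene Adm, with a log2 difference of −1.44 ± 0.35 (SE, adjusted p = 0.112) between means of 4.35 and 5.79, both within the range of the skeletal muscle genes. Adm passed without lateral replicate 1 (log2 difference −1.01, adjusted p = 0.00959, range over such fits up to 0.288), with 1 row per gene (0.0306) and with only the named rows (0.0351), and in 0 of the 7 other alternatives with all samples (up to 0.149). The camera adjusted p-values of the 4 lists were 0.472, 0.843, 0.654 and 0.476. The immediate early gene Egr1, singled out after its values were seen, stood at 10.1 in medial replicate 1 and between 7.33 and 8.22 in the other 5 samples.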

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

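The count over only the rows with a gene name was chosen after the data were seen, and the other alternatives before. The direction of the called genes taken by the naming rule was kept in every alternative run. The count of 717 rows ranged from 0 to 538 with samples left out, and that of 628 rows at 1.5-fold from 0 to 517. The 0 came from limma with both samples numbered 3 left out and the replicate block, which left 4 samples, and 3608 rows had an unadjusted p under 0.05 there. With all samples and the threshold of 0.05 the count lay between 481 and 1033, and at an adjusted p of 0.10 it was 1036. Of the 717 rows, 705 passed after quantile normalization and 700 after centring. When only the 16015 rows with a gene name were tested, 934 passed. They included 600 of the 717 rows, and the remaining 117 have no gene name and were not tested there. Of 564 called genes, 230 kept their call in each of the 6 fits with a sample left out, and all 564 kept their sign. Of 106 genes taken by the naming rule that did not pass, 15 passed in an alternative with all samples at the same threshold and 8 in a fit with a sample left out. The calls of the medial and lateral column lists held in camera except with an estimated correlation (adjusted p = 0.293 for both), with fry at 0.000885 for both. With 1 or 2 samples left out, their adjusted p ranged from 1.49e-13 to 0.00292 and from 1.48e-20 to 4.01e-06. Of the 29 other lists, 3 passed, 0 with an estimated correlation, where floor plate genes had an unadjusted p under 0.05, and between 2 and 5 with samples left out. In fry 4 of them passed, and the lists of ETS and LIM factors and of Eph receptors and ephrins (adjusted p = 0.00263 and 0.0422) did so there but not in camera. Fewer samples lower the counts by construction, and the cause of the other changes was not tested.

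The replicate numbers, and a second number that the labels share between one medial and one lateral sample, were not taken as pairs in the main test. Whether they mark pairs could not be settled. The deviations of same-numbered samples from their group means correlated with r = 0.35, 0.07 and 0.02 over rows. Between medial and lateral samples of different numbers r ran from −0.37 to 0.30. Of the 6 samples, 4 correlated best with their own number. With the replicate block, 481 rows passed, and 477 at 1.5-fold, and with a random replicate block 990 rows passed. The replicate block kept 434 of the 717 rows and the random block all 717. Of the 95 called genes taken by the naming rule, 79 kept their call with the replicate block. Of the 16 that did not, Dscam (adjusted p = 0.0649) was the 1 whose call held in each fit with a single sample left out. Signal over background is not recorded in the table, so low levels, such as those of skeletal muscle genes up to 7.44, cannot be separated from background.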

Other observations

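The split of the samples was a test chosen before the data were examined, and the tests of gene families, neighbouring genes, other cell types and Hox genes were chosen after results had been seen. The 9 families below were picked from the called genes, so their p-values are no independent evidence.

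Of 28 measured neuropeptide genes, 2 were higher and 7 lower in the medial samples, and 19 did not pass. Uts2 and Adcyap1, the gene of pituitary adenylate cyclase-activating peptide, were 11.98-fold and 3.53-fold higher in the medial samples. Sst, Npy and Penk, the genes of somatostatin, neuropeptide Y and enkephalin, were 7.67-fold, 4.07-fold and 2.61-fold higher in the lateral samples, with Gal at 2.17-fold, Cartpt at 2.01-fold, Grp at 1.71-fold and Pnoc at 1.41-fold. Of 18 GABA and glycine receptor subunits, 7 were lower and 0 higher, led by Gabra5 at 3.34-fold, Gabra4 at 2.82-fold and Glra2 at 2.47-fold in the lateral direction. Of 71 potassium channel genes, 8 were lower, led by Kcnh1 at 3.37-fold, and 1, Kcnip3, was 1.46-fold higher. Of 16 synaptotagmins, 4 were lower and 0 higher, with Syt4 at 3.71-fold, Syt6 at 1.85-fold, Syt2 at 1.64-fold and Syt5 at 1.40-fold in the lateral direction. Adjusted over the 9 families, camera gave 0.00429, 1.36e-08, 0.00429 and 2.48e-05 for these 4, and adjusted p = 0.277, 0.083, 0.0967 and 0.083 with an estimated correlation. Of 19 nicotinic and muscarinic receptor genes, 2 were higher and 1 lower, with Chrna3 and Chrnb4 2.20-fold and 1.90-fold higher in the medial samples and Chrm3 10.7-fold higher in the lateral samples. As for other genes with a dim group in the range of skeletal muscle genes, the folds of Uts2 and Chrm3 can understate the difference. Called genes with both group means in that range include Glra3, Gabrq, Kcnh1, Kcna4, Kcnh7, Kcnip3, Grm8 and Grm3. Of 19 glutamate receptor subunits, 3 were higher (Gria3, Grin2c and Grin2d) and 5 lower (Grik1, Gria2, Grid1, Grm8 and Grm3), and neither this family (adjusted p = 0.309) nor the acetylcholine receptors (0.927) passed. The calls of Gabra4, Gal, Cartpt, Grp, Pnoc, Penk, Chrna3 and Chrnb4 ended without at least 1 sample, with largest adjusted p-values of 0.077, 0.0536, 0.136, 0.0983, 0.117, 0.124, 0.105 and 0.133. Medial replicate 1 ended each of them except Gabra4, which ended without medial replicate 3, lateral replicate 1 or lateral replicate 3. The calls of Kcnip3, Syt6, Syt2 and Syt5 ended without any one of the 6 samples, with adjusted p-values of up to 0.153, 0.136, 0.166 and 0.13, and among the glutamate receptor subunits the call of Grik1 held in each of these fits and the others did not.

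Of 6 Iroquois homeobox genes, 4 were higher and 1 lower. Irx2, Irx1, Irx3 and Irx5 were 4.02-fold, 3.68-fold, 2.001-fold and 1.65-fold higher in the medial samples, and Irx6, which lies in the same cluster as Irx3 and Irx5, was 7.54-fold higher in the lateral samples. Camera gave the family an adjusted p of 7.03e-04, and an adjusted p of 0.083 with an estimated correlation. Of 9 Teashirt and zinc finger homeobox genes, 2 were higher and 4 lower. Tshz1, Tshz3 and Tshz2 were 3.19-fold, 1.93-fold and 1.56-fold higher in the lateral samples, with Zeb2 at 1.54-fold, and Zfhx4 and Zfhx3 were 3.60-fold and 2.43-fold higher in the medial samples. Of 18 Sox genes, 2 were higher and 1 lower, with Sox5 at 1.96-fold and Sox2 at 1.55-fold in the medial and Sox6 at 4.66-fold in the lateral samples. These 2 families had camera adjusted p-values of 0.189 and 0.751. The calls of Irx5, Zfhx4 and Zfhx3 ended without medial replicate 3, with largest adjusted p-values of 0.0702, 0.0604 and 0.0504, and that of Irx5 also without medial replicate 1 or lateral replicate 2. Those of Zeb2 and Sox2 ended without any one of the 6 samples (up to 0.133 and 0.113). The direction of each call in the 9 families was kept after quantile normalization and after centring.

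Called genes lay side by side in the genome more often than chance placement gives. Of 14809 neighbouring pairs of measured genes, 60 had both members called, 49 of them in the same direction, where 10000 shuffles of the calls among genes of similar level gave a mean of 11.9 and at most 27 such pairs (permutation p = 1e-04, the smallest they can give). Without pairs that overlap or whose symbols share their first 3 letters, such as Irx1 and Irx2, 40 remained in the same direction against a mean of 10.4 and at most 26. Overlapping genes and neighbours with such shared names therefore do not account for the excess alone. Neighbouring paralogs with unlike names are not removed by this filter, so their part in the excess was not tested. Examples, with log2 differences of the neighbours, are Lhx3 with Nacc2 at 1.17, Klhl1 with Dach1 at 1.17, Tshz1 with Zadh2 at −1.24, and the run of Pdzrn3, Cntn3 and Chl1 at −1.50, −1.55 and −1.88. The hypothesis that some genes may change with a strongly regulated neighbour stays open, as do signal shared between neighbouring transcripts and the clustering of genes of related function.

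Some called genes are on lists of other cell types, so other cells in one group could be a source. The lists could not decide this, because few of their genes lay above every skeletal muscle gene, with 4 of 9 floor plate genes, 3 of 13 neural crest and Schwann cell genes and 3 of 13 sensory ganglion genes, at highest means of 9.97, 12.1 and 10.1. Of these few, 3 of the 4 floor plate genes were called as lower, with a median log2 difference of −1.05 (SD over genes 0.47), and over the whole list the median deviation from each gene's mean was 0.285, 0.0977 and 0.149 in the lateral samples against −0.084, −0.181 and −0.0843 in the medial samples. The median was −0.12 (SD 1.12) for the neural crest and Schwann cell genes, where Gfra3 was called, and 0.16 (SD 1.18) for the sensory ganglion genes, where Neurod1 was called, and over both whole lists the medial and lateral samples overlapped in their median deviations, with lateral replicate 3 highest at 0.177 and 0.13. All 3 sources stay open, as does expression of these genes in the motor neurons themselves, which was not tested, although the sort for green fluorescence is meant to remove such cells, and another list held 2, 5 and 2 of the genes.

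More caudal tissue in the medial samples is a candidate explanation for the excess of Hoxc13, Hoxb13 and, short of the threshold, Hoxc12. The anterior Hox genes of groups 4 to 8 had a median log2 difference of 0.10 (SD over 13 genes 0.27), which does not separate this from a difference between the columns at one level, and Hoxd13, looked up after the other values were seen, at 5.86 and 5.73, was too low to decide. The median deviations of groups 4 to 8 from each gene's mean overlapped between the columns. They were 0.197, −0.112 and 0.0366 in medial replicates 1, 2 and 3 and 0.203, −0.0693 and −0.177 in lateral replicates 1, 2 and 3. Genes of groups 9 to 11 went both ways, with Hoxb9 at 0.73 (limma adjusted p = 0.0884), Hoxa11 at −0.47 and Hoxd10 at −0.55. The call of Hoxb13 ended in 5 of the fits with a sample left out. The level of the dissection is not recorded in the labels for single samples, so the explanations cannot be told apart.

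For the count of 717 rows, the 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many rows, and the highest count of the others was 0.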
